A study of Homo sapiens with 6 samples.

How the data were processed

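Polyadenylated RNA from 6 cultures of BeWo cells was sequenced, 3 with control shRNA and 3 with OVOL1 shRNA, all given 250 µM 8-bromo-cAMP. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a TruSeq kit. Whether the libraries or the counting kept the strand is not given in the sources used here, so a gene and an antisense or overlapping partner cannot be told apart. The authors deposited 1 table with 57771 gene regions, and each set of columns was matched to its library by the index barcode given in the labels. Per the file headers, the table gives for each library a count of unique gene reads (reads with a single mapping place), a count of total gene reads and an RPKM value. The aligner, its version and the annotation release are not given in the sources used here. The build is hg19, per the submitters' processing notes, and positions are printed as the deposited table gives them.

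The deposited RPKM values were checked against the deposited counts. They follow from the total gene reads and the full length of each region from start to end, introns included (implied length over region length 1.00002 to 1.00003). This gives the divisor alone, and whether intronic reads were counted was not tested. Of the 57771 regions, 33211 overlap another. In 1849 of 2166 nested pairs (85.4%, among those with at least 100 unique reads) the larger region held at least as many unique reads as the smaller. In the rest it held fewer, so reads of a nested region were not always counted in the larger one too, and how many reads overlapping regions share was not measured. Total gene reads summed to between 25450250 and 28640098 per library, of which 87.4% to 88.3% were unique, and 3.14% to 3.83% lay on the mitochondrial genome. In 19059 regions there were no reads in any library, and no row lacked a gene name. Gene types came from matching symbols and synonyms to RefSeq names of GRCh38, without coordinates, which found 33529 regions and 19168 of them protein-coding.

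Total gene reads were chosen for the main test because the deposited RPKM rests on them. Counts were scaled by TMM, filtered with filterByExpr at its default settings (23047 regions kept, 0.132% of the reads left out) and tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested regions and a threshold of 0.05. TMM factors were 0.944 to 0.976 in control libraries and 1.03 to 1.04 in OVOL1 shRNA libraries. CPM values use these factors. The SE of a log2 fold change is its size divided by the square root of the test's F. Gene lists were tested with camera in limma on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over 20 lists with at least 5 tested members. They covered syncytiotrophoblast hormones, pregnancy-specific glycoproteins, cell fusion, steroid synthesis, cytotrophoblast progenitors, extravillous trophoblast, the cell cycle, cAMP response, cell-cell junctions, mesenchymal genes, the WNT pathway, interferon response, p53 targets, hypoxia and glycolysis, heat shock and unfolded protein response, cholesterol synthesis, endothelial and leukocyte markers, mitochondrial transcripts and histones. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

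The groups, tests, lists and the rule for named genes were fixed before the data were examined. Named genes are OVOL1 and its paralogs where listed, then the 10 largest rises and 10 largest falls among called regions with a mean of at least 5 CPM and no overlap between groups. They include up to 4 called members per list by smallest p (up to 6 in the 5 trophoblast lists), and always CGA, all CGB genes, GCM1, ERVW-1, ERVFRD-1, MYC, ID1, TP63, ASCL2, CDH1, ZEB1 and MKI67. This gave 66 regions. Overlaps are named where the other region held at least 20% as many reads. Besides those given with the results, these were KRT18 (KRT8), DDIT3 (MARS), DNAJB9 (PNPLA8), CGB7 (NTF4), CGB and CGB2 (CTB-60B18.6), CDH1 (RP11-354M1.2) and ZEB1 (SPTLC1P1 and ZEB1-AS1). Copies of CGB and PSG genes are uncertain between copies. Of the tested regions 23.7% had no overlap between the groups, where chance gives 10% on average over all equal splits of the libraries. Regions are not independent, so a single split can lie away from this by chance, and the share was not measured in other splits.

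The labels number the replicates 1 to 3 in both groups and say nothing of pairing, so the main fit has no block. The data were checked for it. Deviations from the group means correlated across regions by 0.377, 0.489 and 0.383 between same-numbered libraries and by -0.382 to 0.037 between others, so the numbers were taken to pair the libraries, a pairing that comes from this check. Deviations cancel out within a group, so the low correlations between others are not separate evidence, and regions are not independent. Adjusted p-values with the replicate block rest on this pairing and may be too small. No 2 libraries agreed within counting noise. Alternatives were a fit with the replicate block, DESeq2, median-of-ratios factors, library size only, no filter, a filter at 1 CPM in 3 libraries, unique gene reads, limma on log2 of the deposited RPKM plus 1 or 0.1, stricter thresholds, each library left out, and for lists fry and an estimated correlation. The pipeline was tested on simulated data for OVOL1 shRNA against control shRNA over 23047 regions. It recovered 53 of 100 genes changed by 2-fold and 9 of 100 changed by 1.5-fold, called 8 unchanged genes, and called 0 of 50 random lists. The 8 unchanged genes made up a larger share of the simulated calls than the threshold of 0.05 aims at. Genes were simulated independently of each other, so the random lists could not test camera on lists with correlated members. In the lists that camera called, the estimated correlation was 0.161 to 0.886. The simulation covered the fit without the replicate block alone.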

Results

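Transcript levels were measured by RNA sequencing in BeWo cells, a human choriocarcinoma line used as a model of the trophoblast of the placenta. When cyclic AMP signalling is raised, cells of this line leave the state of a dividing cytotrophoblast, fuse and take on features of the syncytiotrophoblast, the hormone-secreting outer layer of the placental villus. Cells carried either a control shRNA or an shRNA against OVOL1 (OVO-like 1, a zinc finger transcription repressor), delivered by lentivirus and selected with puromycin. All cultures received 250 µM 8-bromo-cAMP, a stable cyclic AMP analogue that starts this differentiation, so no undifferentiated cells stood beside them. Each group held 3 independent replicates. The libraries held between 25450250 and 28640098 reads assigned to gene regions, and 23047 regions had enough reads to be tested. The single comparison asked how a lower OVOL1 level alters the transcripts of differentiated trophoblast cells.

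OVOL1 itself was examined first. Its gene lies on chromosome 11 from 65554493 to 65564690 in hg19 coordinates. It stood at 345 ± 90.9 CPM (read count scaled to the size of the library, SD, n = 3) with control shRNA and at 141 ± 38.3 CPM (SD, n = 3) with OVOL1 shRNA, 2.45-fold lower, which left 40.9% of the control level. The log2 fold change was -1.29 ± 0.23 (SE, adjusted p = 0.0256, edgeR), with a lower level in 3 of 3 same-numbered pairs and no overlap between the groups. The separate libraries gave 449, 279 and 307 CPM in control replicates 1, 2 and 3, and 185, 122 and 116 CPM in OVOL1 shRNA replicates 1, 2 and 3. The paralog OVOL2 had similar levels in both groups, 67.1 ± 10.3 and 69.2 ± 7.12 CPM (SD, n = 3, log2 fold change 0.04 ± 0.13 SE, adjusted p = 0.912), although its region overlaps those of SNX5 and MGME1. The OVOL1 region overlaps that of RP11-770G2.5, so the level left of OVOL1 carries the same limit. With a single library left out the OVOL1 fold change ran from -1.54 to -1.04. Its adjusted p was then above the threshold without control replicate 1 (0.0853) or 3 (0.0871) and without OVOL1 shRNA replicate 2 (0.066) or 3 (0.121). The call was also lost with limma on the deposited RPKM values (adjusted p = 0.088 with a pseudocount of 1 and 0.0822 with 0.1).

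Cells with OVOL1 shRNA had lower levels of many genes that mark the syncytiotrophoblast, among them retroviral envelope genes of cell fusion, hormone subunits and enzymes of steroid synthesis. Far fewer regions rose than fell. At an adjusted p under 0.05, 108 regions were higher and 505 were lower in OVOL1 shRNA, and with at least a 2-fold change the numbers were 21 and 235. Some regions overlap, and the 613 called regions formed 543 separate loci, 100 higher and 443 lower. With the replicate number as a block, a pairing taken from these same data, 1627 regions were higher and 2260 lower. Each of the 613 calls was made again in the same direction. When libraries were scaled by their size alone, 256 were higher and 369 lower, and the median log2 fold change of all regions moved from 0.003 to 0.108. Block and library size together turned the excess around, with 2962 higher and 1557 lower. Leaving out a library moved the numbers of higher and lower regions to 11 and 95 (control replicate 1), 3 and 42 (control replicate 3), 13 and 165 (OVOL1 shRNA replicate 1), 79 and 267 (OVOL1 shRNA replicate 2) and 4 and 37 (OVOL1 shRNA replicate 3). Without control replicate 2 they were 120 and 721. Of the 55 named genes called besides OVOL1, 23, 54 and 9 stayed past the threshold without control replicates 1, 2 and 3, and 33, 36 and 11 without OVOL1 shRNA replicates 1, 2 and 3, and none changed direction.

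**Figure D1:**
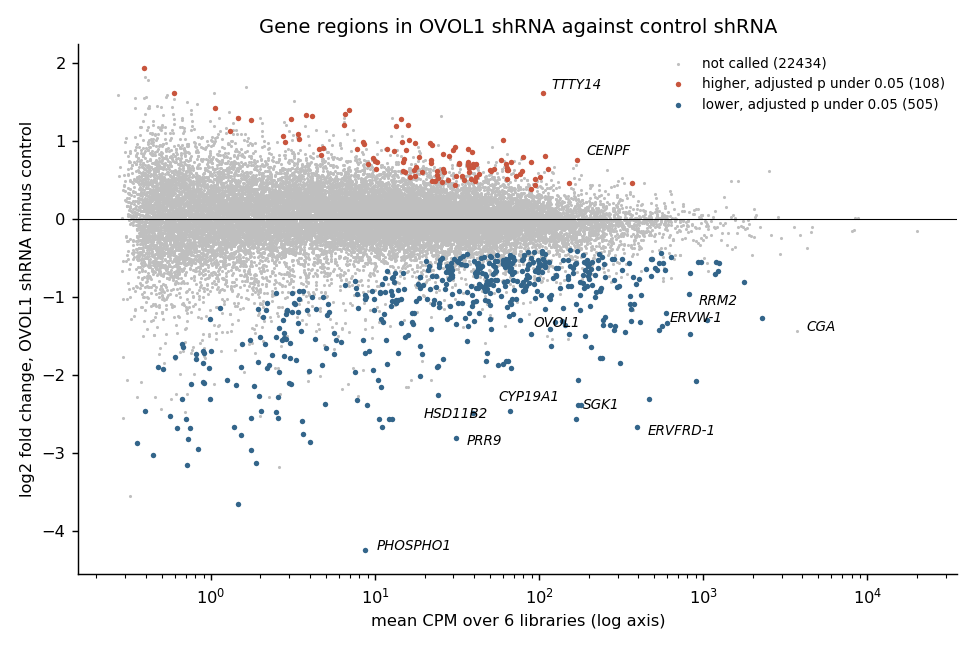
Log2 fold change of each tested gene region (y axis, OVOL1 shRNA minus control shRNA) against its mean CPM over the 6 libraries (x axis, log scale). The 505 regions called lower (blue) reach larger changes than the 108 called higher (red), and CGA, at the right, is among the regions not called (grey).

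Several genes of cell fusion fell, and 1 of them, ERVFRD-1, was among the 10 largest falls that were named. Of 18 tested members of this list, 8 fell, 0 rose and 10 were not called, and OVOL1 itself is one of the 8. ERVFRD-1, which encodes the envelope protein syncytin-2, fell from 679 ± 235 to 107 ± 41.3 CPM (SD, n = 3), 6.36-fold lower (adjusted p = 0.0112). ERVW-1, which encodes syncytin-1, fell from 779 ± 79.4 to 292 ± 19.4 CPM (SD, n = 3), 2.67-fold lower (adjusted p = 0.00163). ERVV-1 and ERVV-2, a pair of related envelope genes, fell 3.43-fold and 3.11-fold. The syncytin-2 receptor MFSD2A fell 3.64-fold, from a low control level of 7.49 CPM, and the cell surface proteoglycan SDC1, a syncytiotrophoblast marker, fell 2.56-fold. The regions of ERVW-1, ERVFRD-1 and ERVV-1 overlap AC007566.10, SMIM13 and ZNF702P, and 49.7% of the reads of ERVV-1 mapped to a single place. GCM1, a transcription factor that drives syncytin expression, had 305 ± 58.6 and 222 ± 31.1 CPM (SD, n = 3), a log2 fold change of -0.46 ± 0.15 (SE, adjusted p = 0.16) that passed with the replicate block (adjusted p = 0.00435, alternatives 0.00435 to 0.426). There were 12 lower members and 1 higher when adjusted over the list alone. With the block, 12 were lower and 3 higher. The list stood below the other genes (camera, adjusted p = 6.55e-07), a call lost with an estimated correlation (adjusted p = 0.442). OVOL1, the target of the shRNA, was a member in this test, which was not run without it.

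Hormone genes fell as well. Of 26 tested hormones and secreted products, 10 fell, 0 rose and 16 were not called, where an unadjusted p under 0.05 gave 15 lower and 0 higher and DESeq2 gave 12 lower and 0 higher. All 6 tested genes of the CGB family, which holds the genes for the beta subunit of chorionic gonadotropin, fell, by 2.3-fold (CGB5) to 3.52-fold (CGB7). CGB5 had 819 ± 142 CPM with control shRNA and 357 ± 47.4 CPM with OVOL1 shRNA (SD, n = 3, adjusted p = 0.0112). These copies are nearly identical and their regions overlap, so a value belongs to the family more than to 1 copy. The CGB1 region overlaps those of CGB5 and CGB8, so these values are not separate. From reads with a single mapping place all 6 were again lower and past the threshold, with a median log2 fold change of -1.29 against -1.33 from all reads. For CGB itself only 4.29% of the reads mapped to a single place. INSL4, an insulin-like peptide of the placenta, fell 3.82-fold and the placental growth factor gene PGF fell from 2245 ± 176 to 1290 ± 108 CPM (SD, n = 3, 1.74-fold, adjusted p = 0.0114). SERPINB2 fell 6.4-fold at a low level, 1.3 CPM in controls, with 26.1% of its reads mapped to a single place. CGA, which encodes the alpha subunit of the gonadotropin, had the highest level of these genes, 5448 ± 2241 CPM in controls and 2020 ± 577 CPM with OVOL1 shRNA (SD, n = 3). Its log2 fold change of -1.43 ± 0.32 (SE, lower in 3 of 3 pairs) was not called (adjusted p = 0.0582) but passed with the replicate block (adjusted p = 1.09e-05, alternatives 1.09e-05 to 0.208). Adjusted over the list alone 13 members were lower, and with the block 16 were. The list stood below the other genes (camera, adjusted p = 9.94e-08), which did not hold with an estimated correlation (adjusted p = 0.442). The CGB genes entered the counts and this test as separate members, although they share reads.

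**Figure D2:**
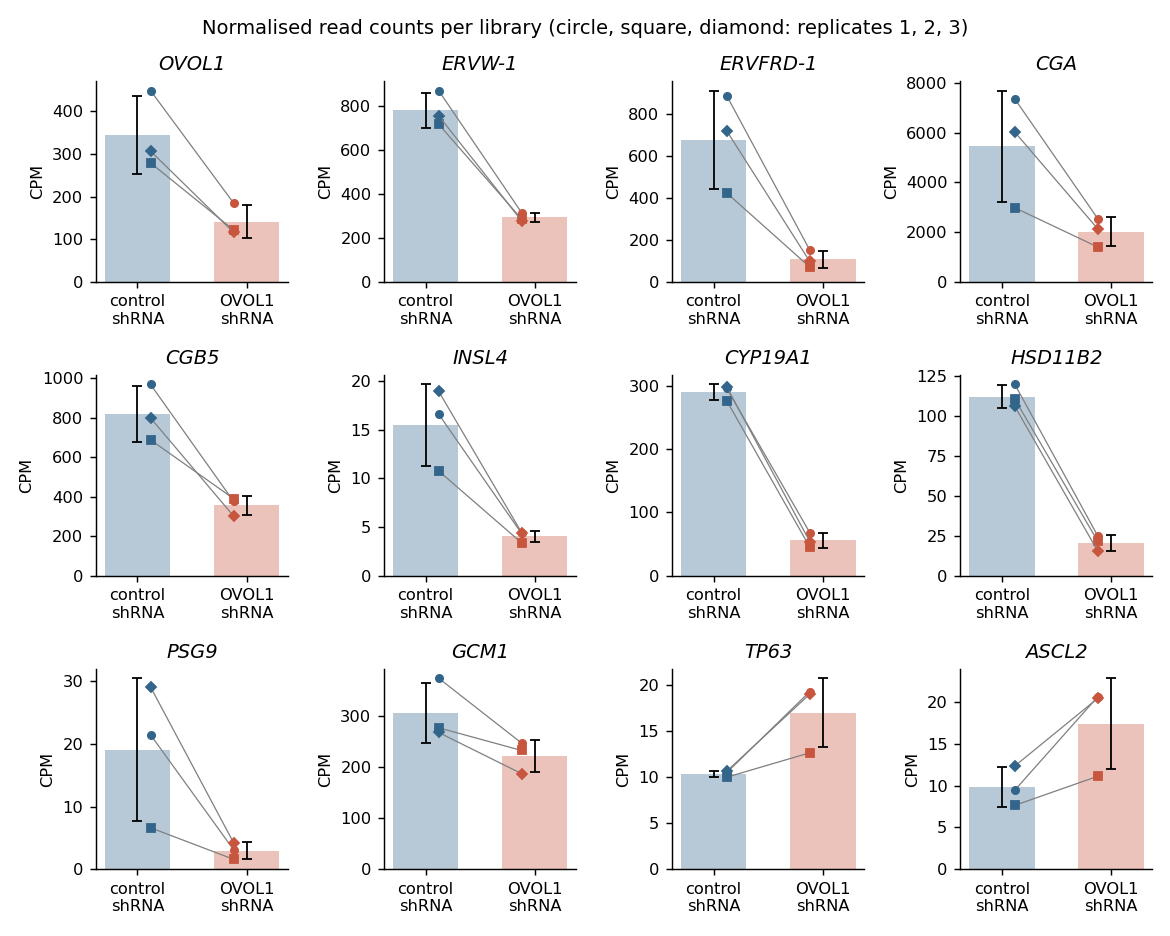
CPM of 12 genes (y axis, linear, each panel with its own scale) in control shRNA and OVOL1 shRNA libraries. Bars show the mean of 3 libraries and error bars 1 SD. Points are libraries and grey lines join those with the same replicate number. HSD11B2 and CYP19A1 differ by much more than the spread of the libraries, while control libraries spread widely for CGA and PSG9, whose lowest control is replicate 2.

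The pregnancy-specific glycoproteins, abundant secreted proteins of the syncytiotrophoblast that were weakly expressed here, showed the largest median change of the 20 lists, a log2 fold change of -2.56 over 6 tested members. PSG2, PSG3, PSG8 and PSG9 fell, 0 members rose and 2 were not called, and an unadjusted p under 0.05 gave 6 lower. PSG9, the most abundant of the 4, fell from 19 ± 11.4 to 3.01 ± 1.34 CPM (SD, n = 3, 6.31-fold, adjusted p = 0.0396). Adjusted over the list alone all 6 were lower, as they were with the replicate block. The genes share much of their sequence and are uncertain between copies. Reads with a single mapping place gave a median of -2.55, with 5 of the 6 called. The list passed camera (adjusted p = 5.93e-06) but not with an estimated correlation (adjusted p = 0.455).

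In steroid hormone synthesis 4 of 14 tested genes fell, 0 rose and 10 were not called. CYP19A1, the aromatase that makes estrogens, fell 5.21-fold, from 290 ± 12 to 55.7 ± 11.6 CPM (SD, n = 3, adjusted p = 0.000851), in a region that overlaps RP11-108K3.1. HSD11B2, which inactivates cortisol, fell 5.47-fold, from 112 ± 7.03 to 20.4 ± 4.81 CPM (SD, n = 3, adjusted p = 0.00151). Smaller falls were found for CYP11A1, the side chain cleavage enzyme that starts steroid synthesis (1.57-fold, adjusted p = 0.0193), and for FDX1, the ferredoxin that passes electrons to it (1.88-fold, adjusted p = 0.011). An unadjusted p under 0.05 gave 5 lower and 0 higher, as did the test adjusted over the list alone, and the block gave 6 lower. The list median of -0.30 lay well above its mean of -0.71, since few members carried the change. Camera gave an adjusted p of 0.000173, and with an estimated correlation the adjusted p was 0.442.

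The genes listed for the cytotrophoblast progenitor state did not move one way. The list also holds keratin genes of simple epithelia, so it is not specific to that state. Of 28 tested members 0 rose and 2 fell. These were KRT18, a keratin of simple epithelia, 1.48-fold lower (adjusted p = 0.0182), and the homeobox gene MSX2, 1.49-fold lower (adjusted p = 0.0272). At an unadjusted p under 0.05, 8 were higher and 6 lower, and DESeq2 called 3 and 3. Counts adjusted over the list alone were 2 higher and 3 lower, and with the block 9 and 9. TP63, a transcription factor of progenitor cells, had 10.4 ± 0.34 CPM in controls and 17 ± 3.76 CPM with OVOL1 shRNA (SD, n = 3), a log2 fold change of 0.71 ± 0.18 (SE, adjusted p = 0.0743). ASCL2 had 9.81 ± 2.37 and 17.4 ± 5.43 CPM (SD, n = 3, log2 fold change 0.83 ± 0.26 SE, adjusted p = 0.142). Both were higher in 3 of 3 pairs and passed with the replicate block (adjusted p = 0.00436 for TP63, alternatives 0.0032 to 0.254, and 0.00185 for ASCL2, alternatives 0.00143 to 0.383). MYC was not called (log2 fold change 0.42 ± 0.22 SE, adjusted p = 0.371), and with the block its adjusted p was 0.0544, 0.0494 with median-of-ratios factors added and 0.0241 with library size only added (alternatives 0.0241 to 0.773). ID1 (0.15 ± 0.24 SE, adjusted p = 0.806) was called neither way (alternatives 0.186 to 0.961). The list as a whole was not called by camera (adjusted p = 0.428), with median and mean log2 fold changes of 0.19 and 0.14. It was called higher without OVOL1 shRNA replicate 2 (adjusted p = 0.019).

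Among 36 cell cycle genes tested, 4 rose, 2 fell and 30 were not called. CENPF, a kinetochore protein, rose from 127 ± 5.95 to 214 ± 14.9 CPM (SD, n = 3, 1.68-fold, adjusted p = 0.0111). The spindle checkpoint kinase gene BUB1B rose 1.75-fold (adjusted p = 0.0146), in a region that overlaps PAK6. The replication licensing factor CDC6 fell 1.95-fold, from 156 ± 29.1 to 79.7 ± 3.13 CPM (SD, n = 3, adjusted p = 0.0151), and RRM2, a subunit of ribonucleotide reductase, also fell 1.95-fold, from 1088 ± 176 to 557 ± 63.6 CPM (SD, n = 3, adjusted p = 0.0151). MKI67, the proliferation marker, had 301 ± 43 and 334 ± 50.5 CPM (SD, n = 3, log2 fold change 0.15 ± 0.14 SE, adjusted p = 0.647). It was higher in 3 of 3 pairs and passed in 1 of 19 alternatives, the block joined to library size only (alternatives 0.0235 to 0.964). When adjusted over the list alone 8 were higher and 5 lower, and with the block 12 and 7. The list was not called by camera (adjusted p = 0.47).

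Stress and signalling genes fell in part. In the heat shock and unfolded protein response list 5 of 18 tested genes fell and 0 rose, with 6 lower and 0 higher at an unadjusted p under 0.05 and 5 lower and 0 higher by DESeq2. They were the stress-induced transcription factor DDIT3 (2.31-fold, adjusted p = 0.0437), the chaperone cofactor DNAJB9 (2.09-fold, adjusted p = 0.0131), HERPUD1 (1.89-fold, adjusted p = 0.0184), XBP1 (1.65-fold, adjusted p = 0.0186) and SESN2 (1.54-fold, adjusted p = 0.0461). Adjusted over the list alone 5 were lower, and with the block 8. In the cAMP and CREB response list 2 of 25 tested genes fell, the transcription factors JUNB (3.24-fold, adjusted p = 0.0311, in a region that overlaps HOOK2) and ATF3 (1.92-fold, adjusted p = 0.0343). There, adjusted over the list alone, 11 were lower, and with the block 12 were lower and 1 higher. Camera called both lists lower (adjusted p = 0.000816 and 0.000689), and neither was called with an estimated correlation (adjusted p = 0.455 for both). CGA stands in the hormone list too, and SESN2 among the p53 targets. The 13 mitochondrially encoded transcripts, which can follow RNA quality, moved with these lists by a small amount. Their median log2 fold change was -0.17, or -0.06 with scaling by library size alone, and 0 of 13 was called (1 lower at an unadjusted p under 0.05, 0 by DESeq2, 3 lower with the block). Camera called them lower (adjusted p = 0.0358), but not with an estimated correlation (adjusted p = 0.755), nor with scaling by library size alone, nor without control replicate 2, OVOL1 shRNA replicate 1 or OVOL1 shRNA replicate 3 (adjusted p up to 0.329).

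The other lists were not called by camera, with adjusted p from 0.252 for the WNT pathway to 0.8 for the interferon response and leukocyte lists. Of 22 extravillous trophoblast genes tested only the adhesion molecule gene MCAM was called, 1.71-fold lower (adjusted p = 0.0126), and with the block 2 were higher and 7 lower. SESN2 was the single call among 18 p53 targets and ADM, which encodes the peptide hormone adrenomedullin, the single call among 18 hypoxia and glycolysis genes (1.85-fold lower, adjusted p = 0.0244). ADM is also 1 of the 10 lower genes of the hormone list. The block gave 5 higher and 5 lower p53 targets. Adjusted over the list alone, 1 extravillous gene was lower, 3 p53 targets were higher and 3 lower, and 1 hypoxia gene was higher and 1 lower. In 8 further lists edgeR called 0 members. Their counts at an unadjusted p under 0.05, then by DESeq2, were 1 higher and 3 lower, then 0, of 24 cell-cell junction genes and 0, then 0, of 9 mesenchymal genes. They were 1 higher, then 0, of 16 WNT pathway genes, 1 lower, then 0, of 18 interferon response genes, and 5 higher and 1 lower, then 3 higher, of 21 cholesterol synthesis genes. For 5 endothelial genes they were 2 lower, then 1 lower, for 5 leukocyte genes 0, then 0, and for 8 histone genes 1 lower, then 0. Adjusted over the list alone, 1 endothelial gene was lower and none of the other 7 lists had a call. With the block 4 junction genes were higher and 4 lower, and 8 cholesterol synthesis genes were higher and 4 lower. The block also called 2 endothelial genes lower, 1 WNT pathway gene higher and 2 lower, 1 interferon response gene higher and 1 lower, 1 histone gene lower, and 1 hypoxia gene higher and 2 lower, and 0 mesenchymal or leukocyte genes. Camera called the cholesterol list higher without control replicate 3 (adjusted p = 0.0208). The epithelial cadherin gene CDH1 had 464 ± 79 and 558 ± 89.9 CPM (SD, n = 3, log2 fold change 0.27 ± 0.16 SE, adjusted p = 0.427) and passed with the block (adjusted p = 0.0255, alternatives 0.00452 to 0.726). ZEB1, a repressor of epithelial genes, stood at 2.27 ± 0.19 and 2.31 ± 0.6 CPM (SD, n = 3, adjusted p = 0.978).

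**Figure D3:**
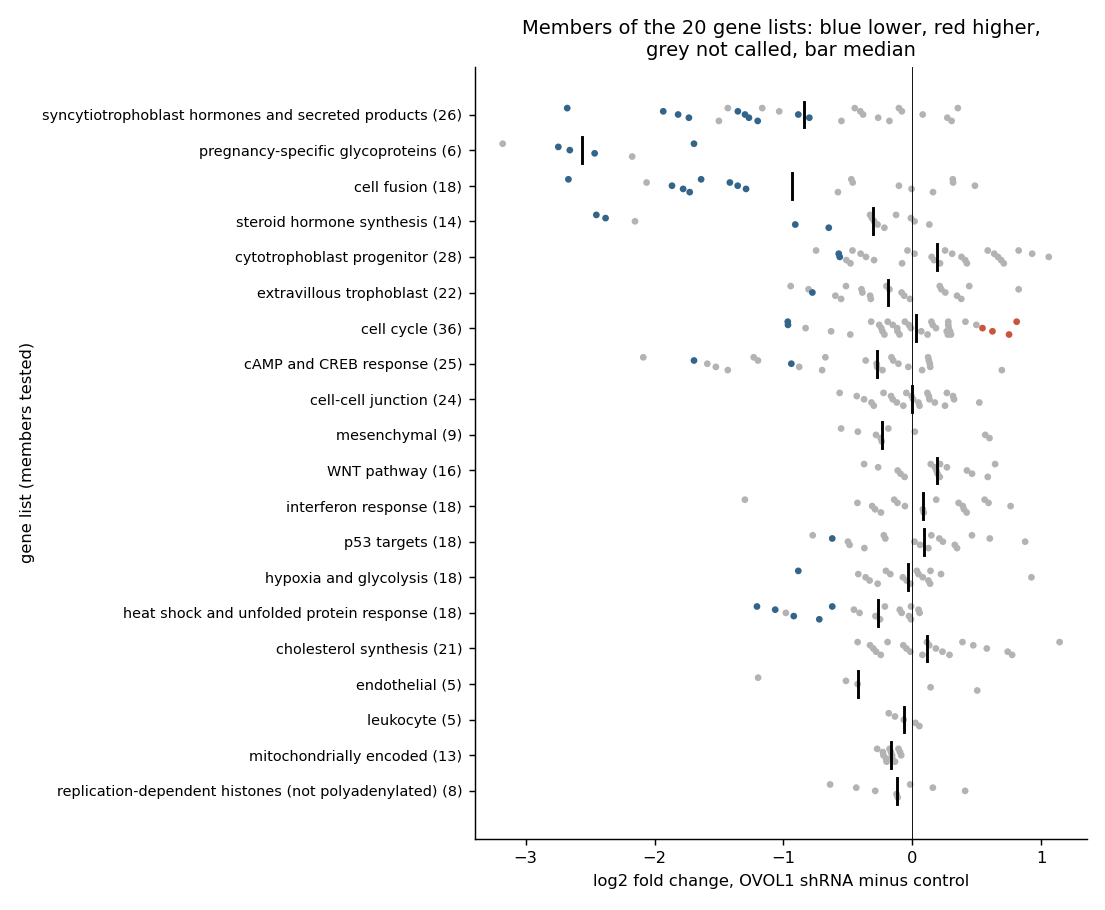
Log2 fold changes (x axis, OVOL1 shRNA minus control shRNA) of the tested members of the 20 gene lists (y axis, number tested in brackets). Each point is a gene, blue where called lower, red where called higher and grey where not called, and the black bar is the list median. The glycoprotein, fusion and hormone medians lie at -2.56, -0.93 and -0.84, while the cell cycle median lies at 0.03 with calls on both sides.

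Outside the lists, the largest called falls among regions with a mean of at least 5 CPM were those of PHOSPHO1, a phosphatase of phosphocholine and phosphoethanolamine, and PRR9. PHOSPHO1 fell 18.9-fold, from 16.6 ± 5.43 to 0.868 ± 0.454 CPM (SD, n = 3, adjusted p = 0.0039), and PRR9 fell 6.99-fold, from 54.1 ± 10.4 to 7.72 ± 3.12 CPM (SD, n = 3, adjusted p = 0.00473). The kinase gene SGK1, which regulates ion transport, fell 5.92-fold, from 286 ± 97.4 to 48.3 ± 19.2 CPM (SD, n = 3, adjusted p = 0.0112). ARHGEF37, RP11-463P17.1 and the overlapping regions BACE2 and PLAC4 fell 5.61-fold to 5.89-fold. Rises were smaller. TTTY14, a noncoding transcript, rose 3.07-fold, from 51.5 ± 13 to 158 ± 17.3 CPM (SD, n = 3, adjusted p = 0.00838). The actin-binding protein gene MISP rose 2.63-fold, the phosphate transporter gene SLC34A2 rose 2.54-fold and S100A10, which binds annexin A2, rose 2.02-fold. GNB4, a G protein subunit gene, rose 2.31-fold, and RP11-145M9.4 and AC007620.3, which overlap each other next to it on chromosome 3, rose 2.44-fold and 2.3-fold. RP11-244F12.3, inside TPM1, rose 2.3-fold, DFNA5 2.01-fold and FAM72B 1.99-fold, the last with 26.3% of its reads mapped to a single place. The adjusted p of these rises lay between 0.00838 and 0.0453. Each was higher in 3 of 3 pairs, which the rule of no overlap between groups fixed in advance.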

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

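Fits restricted to protein-coding regions or to 1 region per overlapping cluster, and those joining the block to another choice, were chosen after seeing the data. The fall of OVOL1 had the same direction in every alternative. Its call was lost with limma on RPKM, at -1.13 (pseudocount 1, adjusted p = 0.088) and -1.18 (pseudocount 0.1, adjusted p = 0.0822), and with 4 of the 6 libraries left out in turn, and it ran from -1.54 to -1.04 with 1 library left out. Regions called higher (108) and lower (505) became 1627 and 2260 with the replicate block, 1703 and 2221 with the block and median-of-ratios factors, 2962 and 1557 with the block and library size only, 209 and 784 with no filter (38712 regions tested), 496 and 1041 with DESeq2, 11 and 27 with limma on RPKM at pseudocount 1, 7 and 30 at 0.1, 21 and 235 with at least a 2-fold change, and 3 and 34 at an adjusted p under 0.01. Library size only gave 256 higher. With 1 library left out there were 3 to 120 higher and 37 to 721 lower. Fewer samples or a stricter threshold account for some of these by construction. For the others the cause was not tested. Median-of-ratios factors, the stricter filter, unique reads, protein-coding regions and 1 region per cluster gave counts within 1.5 times of these. Lists past camera (7) became 0 with an estimated correlation, with or without the block, and were 6 to 8 with 1 library left out. Another question is asked by fry, whether a list moved at all and not whether it moved more than the other genes, and it called 3 lists (hormones, fusion and steroid synthesis, adjusted p = 0.0241). The block changed the calls of CGA, GCM1, TP63, ASCL2 and CDH1 and no other call of a named gene or list. Its pairing came from these same data, so these calls are less sure than their adjusted p-values show. Of the 55 named genes called besides OVOL1, 5 (CYP19A1, ERVV-1, ERVW-1, HSD11B2 and PRR9) stayed past the threshold in all alternatives run on them, and none was reversed. Signs turned for genes that were not called. With 1 library left out ID1 ran from -0.048 (without OVOL1 shRNA replicate 3) to 0.40, OVOL2 from -0.048 (without control replicate 1, and also below 0 without OVOL1 shRNA replicate 2) to 0.16, and ZEB1 from -0.11 (without OVOL1 shRNA replicate 2, and also below 0 without control or OVOL1 shRNA replicate 3) to 0.22. The camera direction (1 up, -1 down) of the interferon response list turned to -1 with library size only and without control replicate 2 or OVOL1 shRNA replicate 3, and it turned to 1 for the cell-cell junction list without OVOL1 shRNA replicate 2 and for the hypoxia and leukocyte lists without control replicate 1. In the fit without the block, simulated 1.5-fold changes were mostly missed (9 of 100 recovered), so a region that this fit did not call may still have changed by that much. The fit with the block was not simulated.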

Other observations

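The tests of explanations in this part, and the gene sets named only here, were chosen after the results had been seen. The region with the smallest p was SLC7A8, a light chain of a transporter of neutral amino acids and thyroid hormone, which fell from 482 ± 7.18 to 134 ± 3.58 CPM (SD, n = 3, log2 fold change -1.84 ± 0.08 SE, adjusted p = 0.000139, edgeR). SLC43A2, another carrier of neutral amino acids, fell from 96 ± 6.92 to 41.4 ± 3.33 CPM (SD, n = 3, adjusted p = 0.00328), and SLC38A9, an amino acid sensor of the lysosome, fell from 383 ± 56.7 to 209 ± 15.3 CPM (SD, n = 3, adjusted p = 0.0151). They were picked out by their values. Over 31 tested amino acid transporter genes, 3 fell and 0 rose, with 6 higher and 7 lower under the replicate block, and the set as a whole was not called (camera, unadjusted p = 0.357). ALAS1, which starts heme synthesis, fell from 196 ± 20.2 to 79.2 ± 1.62 CPM, KHK, the fructose kinase, fell from 21 ± 0.667 to 6.43 ± 0.581 CPM, and the chemokine receptor gene CCR7 fell from 483 ± 61.8 to 178 ± 23.5 CPM (SD, n = 3, adjusted p = 0.00163 for ALAS1 and KHK and 0.0039 for CCR7).

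At an unadjusted p under 0.05 the heat shock and unfolded protein response list had 6 lower genes, and DESeq2 called 5 lower. The list was parted only after its calls were seen. HSPA5 and HSP90B1 were put with the chaperones, while the called chaperone cofactor gene DNAJB9 was not. The parting thus follows the calls in part, and the values of its parts are no separate support. All 10 tested members of endoplasmic reticulum stress and the amino acid response lay below 0, with 5 called lower. Their median log2 fold change was -0.67. Camera gave them an unadjusted p of 5.87e-06, but 0.129 with an estimated correlation and 0.0388 with the block added to it. Of 8 chaperone members 0 were called, with a median of -0.054, 6 below 0 and 2 above. HSPA5, from the chaperone part, and ASNS, from the other part, were singled out here after their values were seen, and were not called. HSPA5, the main chaperone of the endoplasmic reticulum, had 1570 ± 90 and 1559 ± 221 CPM (SD, n = 3, adjusted p = 0.976), and ASNS, a target of the amino acid response, had 49.1 ± 9.19 and 48.7 ± 12.7 CPM (SD, n = 3, adjusted p = 0.986).

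Among cell cycle genes, the 6 calls differed by phase. BUB1, BUB1B, KIF20A and CENPF, which act in mitosis, rose, and CDC6 and RRM2, which act in G1 and S phase, fell. The list was parted by phase only after these calls were seen. With the replicate block 12 G2 and mitosis genes were higher and 1 lower, and 6 G1 and S phase genes were lower and 0 higher. In the members that were not called, 14 of 15 G1 and S phase genes lay below 0 and 13 of 15 G2 and mitosis genes above 0, which became 11 of 15 and 14 of 15 with scaling by library size alone, where the G1 and S phase median moved from -0.19 to -0.085. The mean log2 level of the G2 and mitosis genes minus that of the G1 and S phase genes was higher with OVOL1 shRNA by 0.466 ± 0.021 (SD of 3 pairs, higher in 3 of 3) in these members. This SD rests on the pairing taken from these same data and leaves out the spread between libraries. Over all members, called ones included, the same measure ran from -0.184 to 0.171 in control libraries. It ran from 0.476 to 0.802 in OVOL1 shRNA libraries. A scaling error would move both sets alike, so the difference of 0.466 argues against it as the whole cause. With an estimated correlation neither set, called members included, passed camera (unadjusted p = 0.142 for G1 and S phase and 0.0857 for G2 and mitosis). No measure of cells per phase stood beside the libraries.

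More regions fell than rose. At 2-fold or more, 91.8% of the called regions were lower, and 80.7% were with the replicate block. With scaling by library size alone 78.5% still were lower (95% interval 72.7% to 83.5%, exact binomial, counting error only). Library size joined to the block gave 65.3% (61.2% to 69.2%). With 1 region per overlapping cluster 90.7% were lower (86.1% to 94.3%), which argues against overlapping regions as the whole cause of the excess of large falls. Library size alone moved the median log2 fold change of all regions from 0.003 to 0.108, a small shift beside a 2-fold change. The excess of large falls thus does not rest on the choice between TMM and library size, and a larger scaling error was not tested. Over changes of any size the block gave 58.1% lower, but 34.5% (33.1% to 35.9%) when scaled by library size alone, so the excess among small changes could come from the scaling. The loss of OVOL1, the difference the design names, stays open for the large falls and was not tested apart from the shRNA, since no other OVOL1 shRNA and no rescue stood among these libraries. Of the 10 splits of the 6 libraries into 3 against 3, the real one gave 613 called regions and the highest other 0, where 1 of 10 is too large a share to test chance against 0.05. With the block, the real split gave 3887 and the highest of the other splits that part all 3 pairs, in which the members of 1 pair trade groups, gave 0, and 1 of 4 is again too large a share.

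Libraries of a group did not hold equal OVOL1, and a minority of the regions that fell, larger than among regions not called, ordered them as it did. Among the 504 lower regions other than OVOL1, 15.5% (12.4% to 18.9%, exact binomial) ordered the 3 libraries of both groups exactly as OVOL1 did, and 1 had the reverse order in both. The order in the OVOL1 shRNA group rests on close values, 122 CPM in replicate 2 and 116 CPM in replicate 3. Of the regions not called 3.11% had the order of OVOL1, which argues against an order that most regions of these libraries share. If the OVOL1 left in each library set these levels, regions that rose might show the reverse order, and 3.7% of the 108 did (1.02% to 9.21%) against 3.44% of regions not called, which leaves this open. How far each culture had differentiated, which was not measured apart from these transcripts, would order OVOL1 and the other genes alike and stays open too. Genes are not independent replicates, so these intervals are too narrow.

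The first component of the log2 CPM values held 40.3% of their variance. Control replicate 2 lay nearest to the OVOL1 shRNA libraries on it (-1.03, against -49.7 and -30.4 for the other controls). OVOL1 shRNA replicates 1, 2 and 3 lay at 11.6, 43.8 and 25.7, so replicate 2 was the highest of both groups. The second component (27%) set both replicate 2 libraries (38.93 in control and 25.85 in OVOL1 shRNA) above the others (-34.25 to 3.286). The place of control replicate 2 on the first component thus cannot be told apart from a shift that replicate 2 shares in both groups. Of the 25 called genes of the hormone, glycoprotein, fusion and steroid lists other than OVOL1, 23 were lower in control replicate 2 than in the mean of the other controls, by a median of -0.38 on the log2 scale. Control replicate 1 lay further out the other way, with a median of 0.45 and 3 of 25 lower, and control replicate 3 had 0.04 and 11 of 25. In OVOL1 shRNA replicates 1, 2 and 3 the medians against the other libraries of the group were 0.25, -0.049 and -0.22, with 1, 16 and 19 of 25 lower. Mitochondrial transcripts stood higher in replicate 2 than in the mean of the other libraries of its group, by a median of 0.29 in controls and 0.34 with OVOL1 shRNA.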
